A study of Mus with 10 samples.

How the data were processed

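Nuclei from the left prelimbic cortex, a part of the medial prefrontal cortex, of male and female C57/Bl6J mice were profiled by single-nucleus RNA sequencing with spatial barcodes. Per the labels' protocols, mice received either Chronos, a fast light-gated cation channel (the group called iTBS here), or green fluorescent protein (the control group) in that area. Intermittent theta burst stimulation was given as light: triplets of pulses at 50 Hz every 200 ms, in trains of 2 s with 8 s between trains, for 10 min each hour over 10 hours a day on 3 consecutive days, 30 sessions in all. The contrast of iTBS with control therefore also holds the contrast of the opsin with the fluorescent protein. The interval between the last session and dissection is not given in the sources used here.

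Per the labels' protocols, pieces of frozen cortex from several animals, balanced over sex and group, were embedded together, sectioned and laid on 3 Curio Trekker tiles, from which barcodes released by light enter the nuclei and record their position. Nuclei then went through the 10x Chromium 3' chemistry with dual indices. The nuclei of slides 1 and 2 were divided over 2 lanes each, so that 5 gene expression lanes resulted, and each of the 10 GEO samples pools animals of both groups. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mouse build mm39; their versions and settings are not given in the sources used here. No genome of that build was used here, and no coordinates are printed.

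The deposited tables hold raw counts of unique molecular identifiers (UMIs) per gene and nucleus, made by the authors and not normalised. A combined table and 1 table per slide were deposited; the summed difference between them was 0, and the combined table was used. It holds 24888 nuclei and 32286 features, of which 1 is called Virus. The deposited metadata give each nucleus an animal, a sex, a group, a cell type and coordinates, and these assignments by the authors were taken as they stand. The deposited percent of mitochondrial counts per nucleus reaches 9.99671, so nuclei above about 10 percent are not in the tables. The deposited doublet score reaches 0.552, and 0 nuclei carry the authors' predicted doublet mark; no further doublet caller was run. Only the local coordinates were used, because the global ones take 20064 distinct positions against 24880 for the local ones.

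The replicate was the animal, as named in the metadata: 8 iTBS animals (4 male, 4 female) and 7 controls (2 male, 5 female). Within each group animals were numbered in slide order, and the numbers pair nothing. Slide 1 held 2 iTBS and 3 control animals, slide 2 held 5 and 3, and slide 3 held 1 and 1. Raw counts were summed per animal over all nuclei of a class or annotated type, both lanes together. Animals with at least 10 nuclei entered, and a type was tested with at least 3 animals per group. The Virus feature was left out of library sizes and of these tests. Layer 6b neurons had too few animals for further terms and were fitted with the treatment term alone. Pericytes were not tested, because 1 iTBS animal and 4 controls had enough nuclei.

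The main test was the edgeR quasi-likelihood test with TMM scaling and its filter on low counts, with terms for slide, sex and treatment, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are log2, iTBS minus control, with the standard error taken from the F statistic and left blank where F is close to 0. CPM values are TMM-scaled and given as mean ± SD over animals. The difference in treatment effect between classes of neurons was tested with limma on the difference of log2 CPM (prior count 2) within each animal. A total of 28 gene lists was tested with limma's camera on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of types and the share of same-type nuclei among the 10 nearest nuclei of the same animal were compared by exact two-sided permutation tests of the difference in means, permuting labels within slides (1120 arrangements; for neighbours 672 in layer 5/6 NP neurons and 12 in layer 6b neurons, where animals lacked nuclei of the type). Correlations over 15 animals used 100000 permutations. Intervals of shares are exact binomial 95% intervals and, like the floor of 3 counts used for a group at 0, cover counting error only. Shares of nuclei with a Virus count were also computed after thinning each nucleus to 1000 UMIs.

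The tests, the gene lists, the cell type markers, the alternatives and the rule for naming genes were fixed before the data were examined. The exceptions are the runs without nuclei of the other sex, the medians of lists under other scalings, the tests on the Virus feature, on nuclei of the other sex, on the interferon genes per animal and on the Sst neurons and pericytes of control replicate 1, and the genes described as noted later. By the rule, the 5 genes with the smallest p are named in glutamatergic neurons if fewer than 5 pass, with up to 3 higher and 3 lower genes past the threshold in each other class or type. It adds up to 4 members of each list by smallest p, and in all cases Fos, Arc, Npas4, Egr1, Nr4a1, Bdnf and the sex-linked genes. Of the list members, the first few by p are printed, and the rest are summarised.

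Alternatives were DESeq2, limma-voom, library size without TMM, no filter on low counts, no slide term, no sex term, the number of nuclei as a covariate, at least 50 nuclei, an adjusted p under 0.1, and leaving out each slide and each animal in turn. Of these, the annotated types had only DESeq2, no filter, no slide term and each animal left out. The rest were run in the glutamatergic and GABAergic classes only. The fits were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes. Changed genes were drawn only above a floor of mean counts, and noise was drawn for each gene separately. With 200 true changes the adjusted threshold is also looser, so the recovered shares are not the power of the real tests. In glutamatergic neurons (14870 genes run) 64% of the genes changed by 1.5-fold were recovered, 88% at 2-fold and 98% at 3-fold. In GABAergic neurons (11321 genes run) the shares were 46%, 96% and 100%, and in layer 5/6 NP neurons (6319 genes run) 20%, 64% and 100%. The permutation test gave p under 0.05 in 5% of 400 simulated null draws.

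Total UMIs per animal ran from 3509414 (iTBS replicate 7) to 11790688 (control replicate 3). Slide 3 was shallower, with a median of 1931 UMIs per nucleus against 3721 to 4248 in the lanes of slides 1 and 2. R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 was used, together with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.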

Results

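A total of 24888 nuclei from 15 mice was measured, 13355 from 8 iTBS animals and 11533 from 7 controls, with a median of 3543 UMIs and 1990 genes per nucleus. The authors' annotation divided them into 16 types. Glutamatergic neurons made up 50.1% of nuclei (12466), GABAergic neurons 11.5% (2858) and glial and vascular cells 38.4% (9564). Summed over glutamatergic nuclei, animals had between 2175579 and 8080496 counts, and summed over GABAergic nuclei between 312646 and 1524046.

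The first comparison asked which genes differ in the glutamatergic neurons of the prelimbic cortex after accelerated theta burst stimulation. Of 15112 genes tested, 0 passed an adjusted p of 0.05 in edgeR, 1026 had an unadjusted p under 0.05, and DESeq2 called 1, Sobp (lower, adjusted p = 0.0294). Without the filter on low counts edgeR called 54, of which 53 were also tested with it. The 5 genes with the smallest p did not pass, each at an adjusted p of 0.595 in edgeR. Gfap, the intermediate filament of astrocytes, stood at 3.93 ± 3.72 CPM in iTBS animals and 1.44 ± 0.770 in controls (SD, n = 8 and 7; log2 fold change 1.90 ± 0.36 SE). Rspo3, a secreted enhancer of Wnt signalling, stood at 34.3 ± 3.76 and 24.5 ± 4.06 CPM (0.44 ± 0.09). Sobp stood at 332 ± 31.6 and 402 ± 39.0 CPM (−0.34 ± 0.07), Palmd at 25.0 ± 8.72 and 38.4 ± 15.9 CPM (−0.83 ± 0.18), and Apobec4 at 34.0 ± 9.80 and 47.0 ± 15.6 CPM (−0.58 ± 0.12). Without iTBS replicate 1, Gfap passed (2.10, adjusted p = 0.0348), and without iTBS replicate 2, which had 12.8 CPM, its fold was 1.25 (adjusted p = 0.862). In astrocytes Gfap averaged 427 CPM in iTBS animals and 243 in controls. Whether RNA of astrocytes adds to its counts in glutamatergic neurons was not tested. Simulated changes of 2-fold, in genes above a floor of counts, were recovered in 88% of cases in these neurons, which is not the power of the real test.

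Activity-regulated transcription factors and effectors, the genes that neurons induce within minutes to hours of firing, did not pass in glutamatergic neurons. Fos was at 10.9 ± 5.94 CPM in iTBS animals and 9.71 ± 4.26 in controls, with a fitted log2 fold change of −0.19 ± 0.26 SE (adjusted p = 0.915 in edgeR, n = 8 and 7). The fitted values were −0.13 ± 0.25 for Arc (0.958), −0.37 ± 0.29 for Npas4 (0.834), −0.13 ± 0.17 for Egr1 (0.912), −0.09 ± 0.12 for Nr4a1 (0.925) and −0.17 ± 0.12 for Bdnf (0.805). Without the slide term the fitted value was 0.16 for Fos, 0.12 for Egr1 and 0.0239 for Nr4a1. Of 18 measured immediate early genes, 14 had fitted values below 0 and 4 above, with a median of −0.11 (camera adjusted p = 0.0574), and 1 was called when adjusted over the list alone. Egr4 (−0.51) and Egr2 (−0.82) had the smallest p in that list.

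Lists of postsynaptic, adhesion and late activity-regulated genes lay lower in iTBS animals by camera with its preset correlation, and each of these calls was lost with an estimated one. Of 28 measured scaffolds and kinases of the postsynaptic density, 22 had fitted values below 0 (median −0.11, adjusted p = 0.00629; adjusted p = 0.656 with an estimated correlation), with Camk2d at −0.42 and Homer2 at −0.34. Of 18 ionotropic glutamate receptor genes 14 were below 0 (median −0.10, adjusted p = 0.0141; adjusted p = 0.475 with an estimated correlation), with the NMDA receptor genes Grin2b at −0.24 and Grin3a at −0.32. Of 47 synaptic adhesion genes 32 were below 0 (median −0.08, adjusted p = 0.00629; adjusted p = 0.608 with an estimated correlation), with Cadm1 at −0.33 and Lrrtm3 at −0.21. Of 24 late activity-regulated genes 16 were below 0 (median −0.05, adjusted p = 0.0191; adjusted p = 0.656 with an estimated correlation), with Ptgs2, a prostaglandin synthase, at −0.54 and Sorcs3 at −0.31. Over all genes 0 members of these lists were called, and adjusted over the list alone 1 of the late activity-regulated genes was called and 0 of the others. Metabotropic glutamate receptors went both ways, with Grm4 at 0.47 and Grm5 at −0.28. Of these 7 genes 4 were below 0 (median −0.13, adjusted p = 0.232).

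Another 6 lists lay higher in iTBS animals, again by camera with the preset correlation only. All 20 measured interferon response genes had fitted values above 0, with a median of 0.62 (adjusted p = 7.37e-08; adjusted p = 0.588 with an estimated correlation). They include the interferon-induced Ifi44 (1.89 ± 0.56 SE), the signalling factor Stat2 (0.47 ± 0.18) and the class I antigen H2-K1 (1.01 ± 0.41), and 0 members were called over all genes or adjusted over the list alone. The interferon mean per animal rose with microglia transcripts in the same nuclei (r = 0.624, permutation p = 0.0142, n = 15), as described below. Splits of the animals, also described below, gave a camera p as small for this list in 24 of 100. Of 83 ribosomal protein genes 77 were above 0 (median 0.13, adjusted p = 3.12e-05; adjusted p = 0.749 with an estimated correlation), and of 75 nuclear genes of oxidative phosphorylation 67 were (median 0.10, adjusted p = 0.00312; adjusted p = 0.766 with an estimated correlation). Of 7 oligodendrocyte transcripts 6 were above 0 (median 0.45, adjusted p = 0.00312; adjusted p = 0.656 with an estimated correlation), with St18 at 1.10 and Mbp, a main myelin protein, at 0.58. Of 17 myelin genes 16 were above 0 (median 0.38, adjusted p = 0.0141; adjusted p = 0.677 with an estimated correlation), and of 12 microglial activation genes 10 were (median 0.34, adjusted p = 0.0101; adjusted p = 0.475 with an estimated correlation). By fry, 0 of the 28 lists passed, and without the slide term camera called 1. The oligodendrocyte transcripts are a list of another cell type, and the myelin and microglial activation lists also hold glial genes. Mbp averaged 129 CPM in iTBS animals and 101 in controls here, against 2294 CPM in pooled oligodendrocytes. Whether RNA of glia adds to these lists in glutamatergic neurons was not tested.

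The other lists did not pass in glutamatergic neurons. Among them, the lists of microglia, astrocyte, GABAergic and striatal transcripts hold genes of other cell types or tissue. Lists with medians above 0 were reactive astrocyte genes (7 of 10 above 0, median 0.22, adjusted p = 0.071), glycolysis (16 of 20, 0.08, 0.0582) and microglia transcripts (5 of 8, 0.14, 0.139), with the complement gene C1qa at 0.74. Glucocorticoid-responsive genes (13 of 17, 0.03, 0.308), presynaptic release machinery (22 of 34, 0.03, 0.297), heat shock genes (15 of 23, 0.06, 0.433) and astrocyte transcripts (5 of 7, 0.09, 0.565) were also above 0 in the median. Actin and spine regulators were split evenly (15 of 30 above 0, median 0.01, adjusted p = 0.863). Lists with medians below 0 were GABA receptors (13 of 19 below 0, −0.04, 0.071), with Gabra2 at −0.46, GABAergic transcripts (5 of 6, −0.16, 0.249) and axon guidance (21 of 40, −0.03, 0.768). Potassium channels (18 of 33, −0.02, 0.591) and sodium and calcium channels (17 of 30, −0.01, 0.646) had medians just below 0, and library size alone in place of TMM, which shifts the median of all genes by 0.0257, brings both above 0. The median and the mean differed in sign for mitochondrially encoded transcripts (9 of 13 above 0, median 0.02, mean −0.01, camera up, adjusted p = 0.591) and for core clock genes (9 of 17, median 0.02, mean −0.01, camera down, 0.771). For striatal projection neuron transcripts, from tissue next to the cortex, the median was 0.14 and the mean 0.01 while camera pointed down (3 of 6 above 0, adjusted p = 0.771). Adjusted over the list alone, 1 gene was called in each of the lists of potassium channels, reactive astrocyte, oligodendrocyte, astrocyte and microglia transcripts, and 0 in the others named here.

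**Figure D1:**
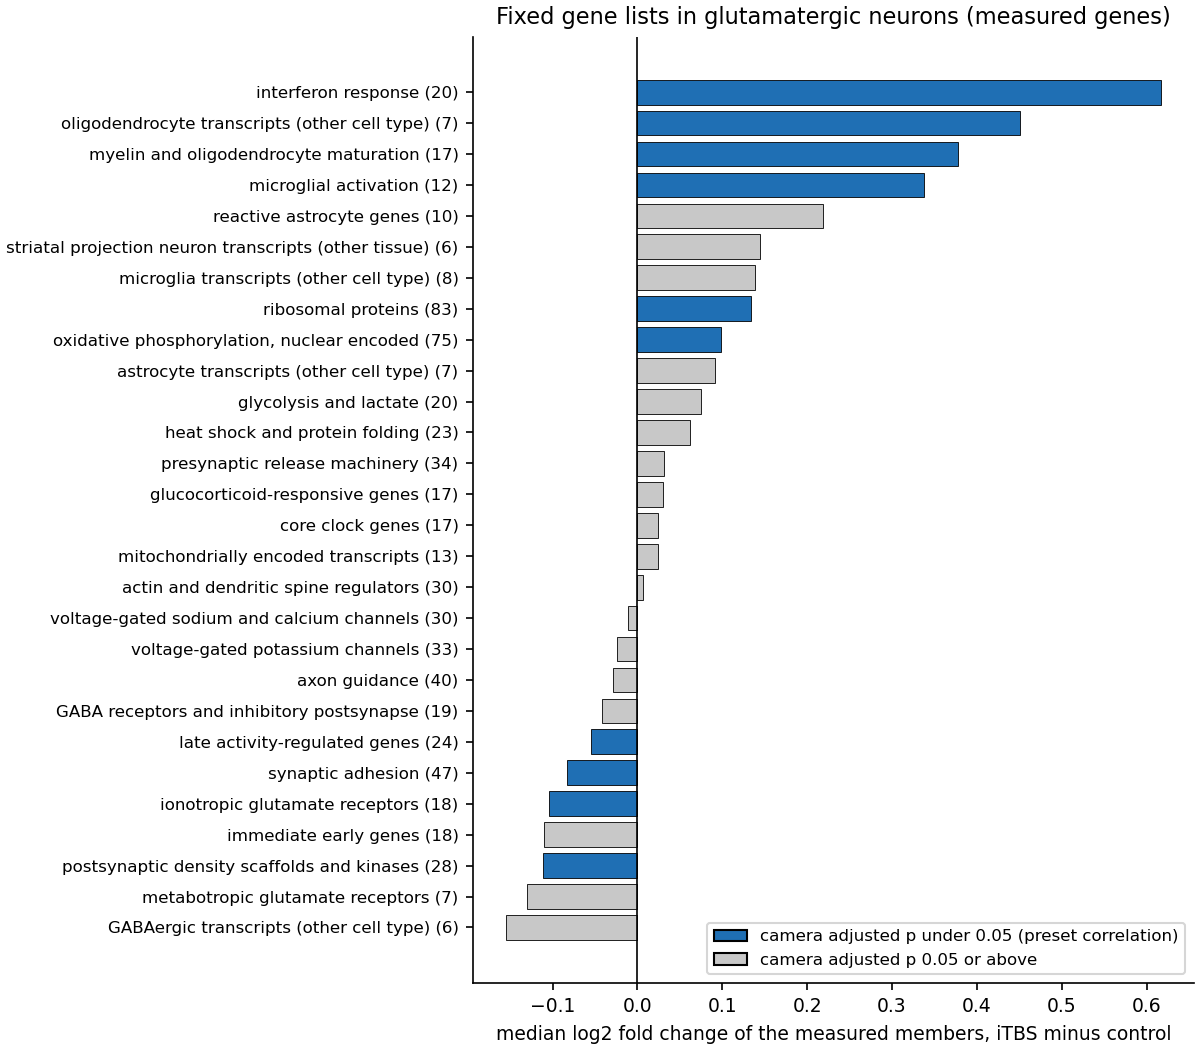
Bars give the median fitted log2 fold change (iTBS minus control, x axis) of the measured members of each of the 28 lists in glutamatergic neurons of 8 iTBS and 7 control animals, with the number of measured genes in brackets and the colour showing camera's adjusted p with the preset correlation. The interferon response list has the median farthest from 0, at 0.62.

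In GABAergic neurons 0 of 11563 genes passed in edgeR, 627 had an unadjusted p under 0.05, and DESeq2 also called 0. Simulated changes of 2-fold, in genes above a floor of counts, were recovered in 96% of cases in this class, which is not the power of the real test. Without slide 3, 1 gene passed, and without the filter on low counts 62 did, 59 of them also tested with it.

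Within annotated types, 6 genes passed, all lower in iTBS animals, against 404 without the filter on low counts. In layer 5/6 near-projecting (NP) neurons these were Npy and Sst, neuropeptides of interneurons, and Adarb2, an RNA-binding protein gene that marks interneurons of the caudal ganglionic eminence. Npy averaged 11.9 ± 20.8 CPM in 8 iTBS animals and 263 ± 600.5 in 6 controls (log2 fold change −4.84 ± 0.67 SE, adjusted p = 6.04e-05 in edgeR). Sst averaged 12.5 ± 15.8 and 121 ± 270 CPM (−3.55 ± 0.60, adjusted p = 0.00196). Adarb2 had 74 counts in controls and 0 in iTBS animals, and control replicates 4, 5 and 6, the controls of slide 2, also had 0. The pooled control level was 38.7-fold above a floor of 3 counts over the iTBS group, or 23.3-fold without control replicate 3 (adjusted p = 0.0183 in edgeR with all animals). The counts lay in few nuclei, so this fold is not a lower bound. Single nuclei carried most of these counts: 202 of the 204 Npy counts and 88 of the 92 Sst counts of control replicate 6 lay in 1 of its 31 NP nuclei. All 43 Adarb2 counts of control replicate 3 lay in 1 nucleus, and the 26 of control replicate 2 in 3 nuclei. DESeq2 called 0 genes in this type. In edgeR 0 genes passed without iTBS replicate 2, 1 without control replicate 6 and 2 without control replicate 2: Npy and Sst were under the filter on low counts without iTBS replicate 2 or control replicate 6, as was Adarb2 without control replicate 3, and Adarb2 did not pass without control replicate 2 (−5.56, adjusted p = 0.136) or without iTBS replicate 2 (−2.04, adjusted p = 1.00).

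In Sst neurons, the interneurons that express somatostatin, Tll1, a metalloprotease gene, averaged 7.03 ± 8.53 CPM in iTBS animals and 34.9 ± 43.0 in controls (−2.11 ± 0.39 SE). Shisa9, an auxiliary subunit of AMPA receptors, averaged 80.3 ± 39.3 and 235 ± 231 CPM (−1.49 ± 0.28), and both had an adjusted p of 0.0488 in edgeR (n = 8 and 7). Control replicate 1 held the highest level of both genes, 128 CPM of Tll1 and 753 CPM of Shisa9, and in that animal the nuclei annotated as Sst neurons had the lowest Sst, Grin3a and Elfn1 levels of all 15 animals. Without it, 0 genes passed (Shisa9 −0.97, adjusted p = 0.153), and DESeq2 called 0. Also without any of control replicates 5, 6 and 7 or iTBS replicates 1, 2, 5, 6, 7 and 8, 0 genes passed, while 1 passed without control replicate 2 or 4 or iTBS replicate 3, and 6 without iTBS replicate 4. The fold of Tll1 stayed between −2.28 and −1.92 wherever it was tested, and that of Shisa9 between −1.72 and −0.97, while the adjusted p with all animals lay just under the threshold. Tll1 was under the filter on low counts without control replicate 1, so its range always includes that animal.

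In astrocytes, Pigk, part of the transamidase that attaches GPI anchors to proteins, averaged 250 ± 93.0 CPM in iTBS animals and 395 ± 143 in controls (−0.64 ± 0.11 SE, adjusted p = 0.0314 in edgeR, n = 8 and 7). DESeq2 called the same gene (adjusted p = 0.00037). Within each slide all iTBS animals lay below all controls: at 215 to 270 against 373 to 387 CPM on slide 1, 185 to 241 against 283 to 338 on slide 2, and 469 against 707 on slide 3. Pigk had the smallest p of 10062 genes in a fit with a slide term on these data, so this order is not separate support. On slide 3 the control was female and the iTBS animal male. The fold kept its direction without each animal (−0.68 to −0.57). Its adjusted p was above 0.05 without any of control replicates 1, 4, 5 and 7 or iTBS replicates 1, 2, 3, 4 and 8, with 0.252 as the highest value (without iTBS replicate 2), and at 1.00 without the slide term, with a fold of −0.73.

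**Figure D2:**
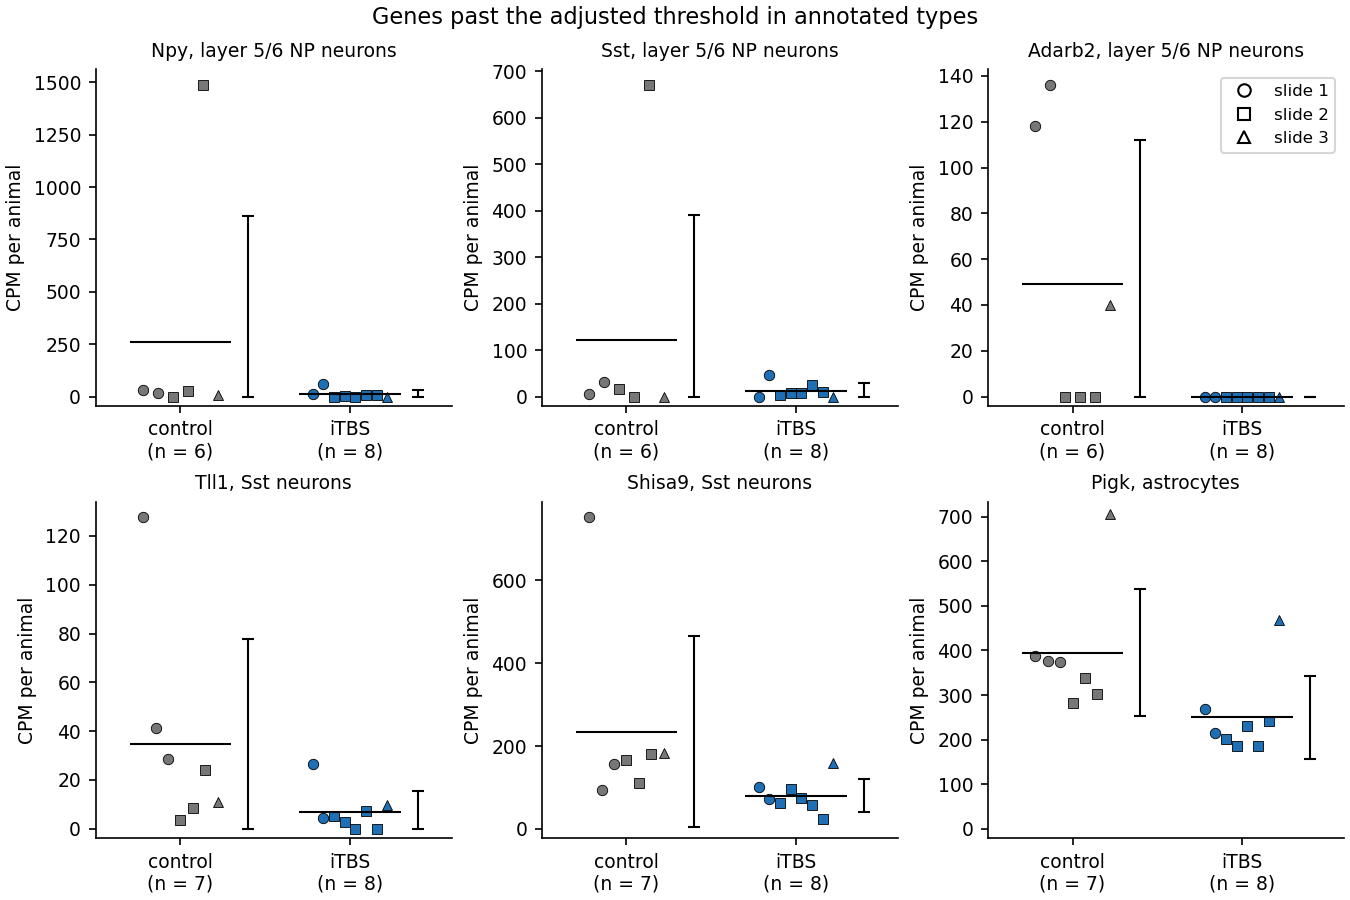
Points give the CPM of each animal (y axis) for the 6 genes past the adjusted threshold in an annotated type, by group on the x axis, with markers for the slide, a horizontal line for the group mean and a bar for 1 SD, drawn no lower than 0. Pigk in astrocytes is lower in iTBS animals within each slide, while Npy and Sst in NP neurons are high in 1 control animal, at 1488 and 671 CPM.

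In the other tested types 0 genes passed in edgeR. Without the filter on low counts up to 64 passed (microglia), with 27 in layer 2/3 intratelencephalic (IT), 60 in layer 5 IT and 35 in layer 6 corticothalamic neurons, and leaving out single animals gave up to 5 (layer 6 corticothalamic neurons). The numbers with an unadjusted p under 0.05 were 578 in layer 2/3 IT neurons, 601 in layer 5 IT, 527 in layer 5 pyramidal tract, 453 in layer 6 IT, 327 in layer 6 corticothalamic and 51 in layer 6b neurons. They were 268 in Pvalb and 335 in Vip neurons, 322 in oligodendrocytes, 169 in their precursors, 361 in microglia and 391 in endothelial cells. DESeq2 called 4 genes in layer 5 IT neurons and 0 in the rest of these types. Whether the types differ in their response was tested between classes only: 0 of 11426 genes had a different treatment effect in glutamatergic and GABAergic neurons by limma (715 with unadjusted p under 0.05; edgeR 0, with 647). Between IT and other glutamatergic neurons, 0 of 12424 genes differed in treatment effect (686; edgeR 0, with 607).

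Lists of glial genes were also tested in their own cell types. All 14 measured reactive astrocyte genes had fitted values above 0 in astrocytes, with a median of 0.65 (camera adjusted p = 5.39e-06; adjusted p = 0.30 with an estimated correlation). The acute phase gene Serpina3n averaged 69.7 against 32.7 CPM (1.14 ± 0.35 SE), H2-D1 was at 0.78, the complement gene C3 at 1.04 and Gfap at 0.76. Over all genes 0 of them were called, and 1 when adjusted over the list alone. Of 14 microglial activation genes in microglia 12 were above 0, with a median of 0.29 (adjusted p = 0.000705; adjusted p = 0.381 with an estimated correlation), with the lysosomal protease gene Ctsb at 0.37 and the class II antigen gene H2-Ab1 at 0.43. Of 19 myelin genes in oligodendrocytes 13 were above 0, with a median of 0.02 (adjusted p = 0.342), and Apod was at 0.30. In these last lists 0 members were called when adjusted over the list alone.

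The makeup of the tissue was compared as shares of each animal's nuclei. Layer 2/3 IT neurons made up 7.60 ± 3.47% of nuclei in iTBS animals and 11.9 ± 6.18% in controls (SD, n = 8 and 7; exact permutation p = 0.113). Oligodendrocytes made up 9.90 ± 3.06% and 7.24 ± 3.54% (exact p = 0.184) and microglia 9.54 ± 4.58% and 7.38 ± 3.01% (exact p = 0.287). Pericytes were at 0.448 ± 0.186% and 2.91 ± 6.03% (exact p = 0.0652), with control replicate 1 alone at 16.6%. After adjustment over the 16 types 0 passed (lowest adjusted p = 0.526), and 0 had an unadjusted p under 0.05. The edgeR test on numbers of nuclei also called 0. Of shares within a class 0 passed after adjustment, and layer 5/6 NP neurons made up 5.98 ± 1.99% of glutamatergic nuclei in iTBS animals and 4.25 ± 1.49% in controls (exact p = 0.0429, adjusted p = 0.429). Layer 2/3 IT neurons made up 15.3 ± 6.53% of glutamatergic nuclei in iTBS animals and 26.0 ± 18.7% in controls (exact permutation p = 0.164). The tests on pooled glutamatergic neurons were not adjusted for this mix of layers.

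**Figure D3:**
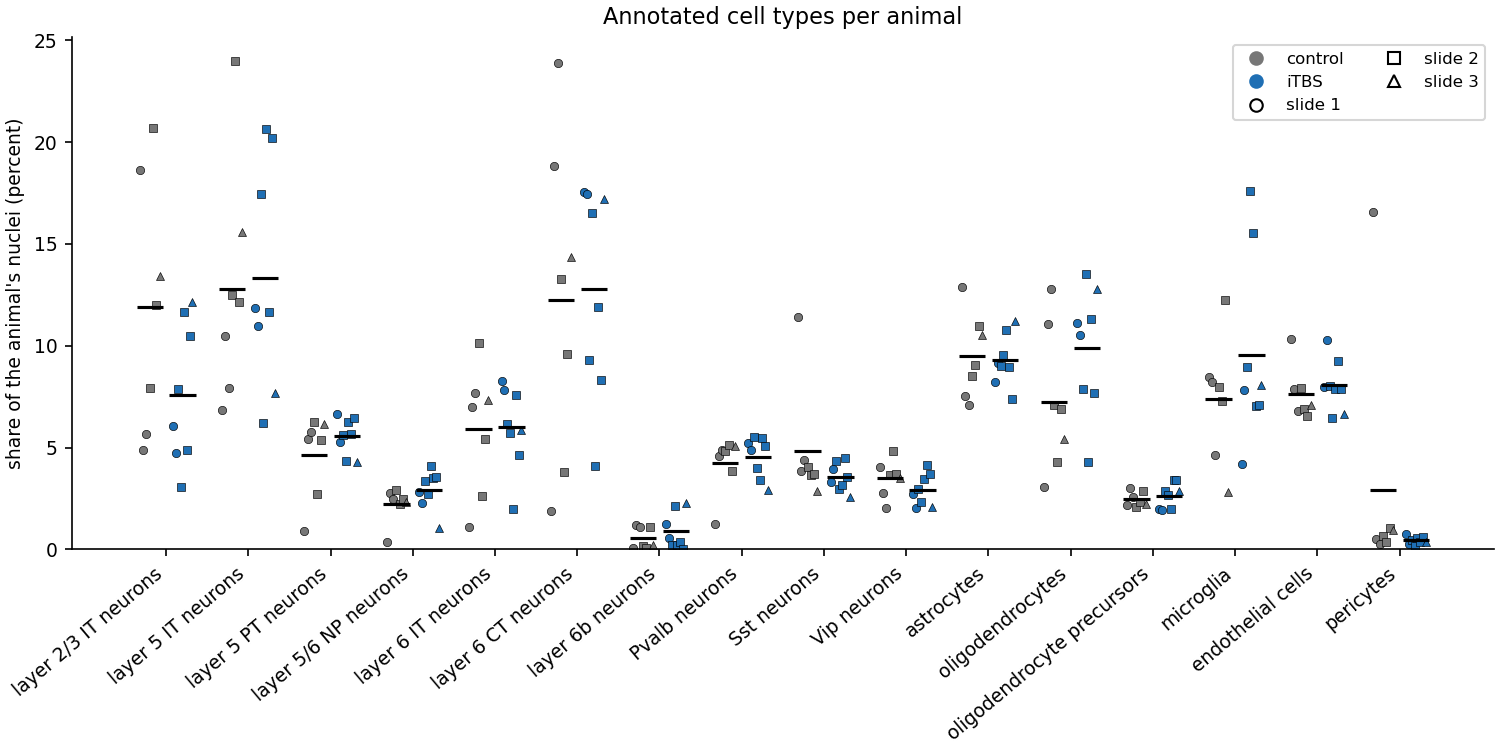
Points give the share of each animal's nuclei (y axis, percent) in each of the 16 annotated types (x axis), coloured by group, with the marker showing the slide and the horizontal lines the group means. The farthest point is the pericyte share of control replicate 1, at 16.6%.

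Spatial arrangement was compared as the share of same-type nuclei among the 10 nearest nuclei of the same animal. Layer 2/3 IT neurons had 28.2 ± 10.3% same-type neighbours in iTBS animals and 38.4 ± 6.86% in controls (SD, n = 8 and 7; exact permutation p = 0.0411), which did not pass after adjustment over 15 types (adjusted p = 0.616). Microglia had 17.3 ± 10.4% and 10.7 ± 5.79% (exact p = 0.188). The measure was not adjusted for the abundance of a type, which went the same way in both. Layer 2/3 IT neurons were 7.60% and 11.9% of nuclei, and microglia 9.54% and 7.38%. In all, 0 types passed and 1 had an unadjusted p under 0.05, which layer 6b neurons, with 12 arrangements, could not reach.

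The sex of the animals was the second factor of the design. In glutamatergic neurons 6 genes differed between sexes in edgeR, all sex-linked, with 799 genes at an unadjusted p under 0.05. Xist, the RNA that silences an X chromosome, was at 1500 ± 205 CPM in 9 females and 236 ± 47.5 in 6 males (log2 fold change, female minus male, 2.66), and Tsix, which overlaps it on the other strand and whose reads may not be told apart, at 139 and 26.1 CPM (2.83). The Y-linked genes were higher in males: Ddx3y at 46.0 ± 5.91 against 9.03 ± 5.41 CPM, Uty at 119 ± 18.1 against 17.7 ± 14.7, Kdm5d at 39.6 against 6.74 and Eif2s3y at 88.8 against 13.7. The treatment effect differed between sexes for 0 genes in edgeR, with 500 at an unadjusted p under 0.05, and for 0 in DESeq2, with 324. Only 2 controls were male, among them control replicate 1, whose makeup stood apart as described below. A difference in response between sexes is therefore not excluded.

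Sex-linked counts were also examined per nucleus. A nucleus was typed female with at least 4 Xist counts and 0 Y-linked ones, and male with at least 2 Y-linked counts and at most 1 of Xist. Of 11702 nuclei typed in this way, 1166 (9.96%) were of the other sex than their animal, with 23.6% in iTBS replicate 3 and 35.1% in iTBS replicate 8. In the male iTBS replicate 8 only 316 of 1720 nuclei were typed. Of its 122 glutamatergic nuclei with at least 5000 UMIs, 32 were of male type and 25 (20.5%) of female type. Xist has more counts than the Y-linked genes, so female nuclei are typed more readily in a shallow section and this share may be raised. Without these nuclei the fold of Xist in glutamatergic neurons was 4.89, 0 genes passed for treatment in glutamatergic and in GABAergic neurons, and 12 lists passed by camera, of which 10 were among those above. Pigk then had a fold of −0.61 ± 0.12 SE in astrocytes (adjusted p = 0.0756). In Sst neurons 0 genes passed, with folds close to those of the full set but larger errors for Tll1 (−2.12 ± 0.55 SE) and Shisa9 (−1.38 ± 0.35, adjusted p = 0.554 each). This run was chosen after seeing the data.

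**Figure D4:**
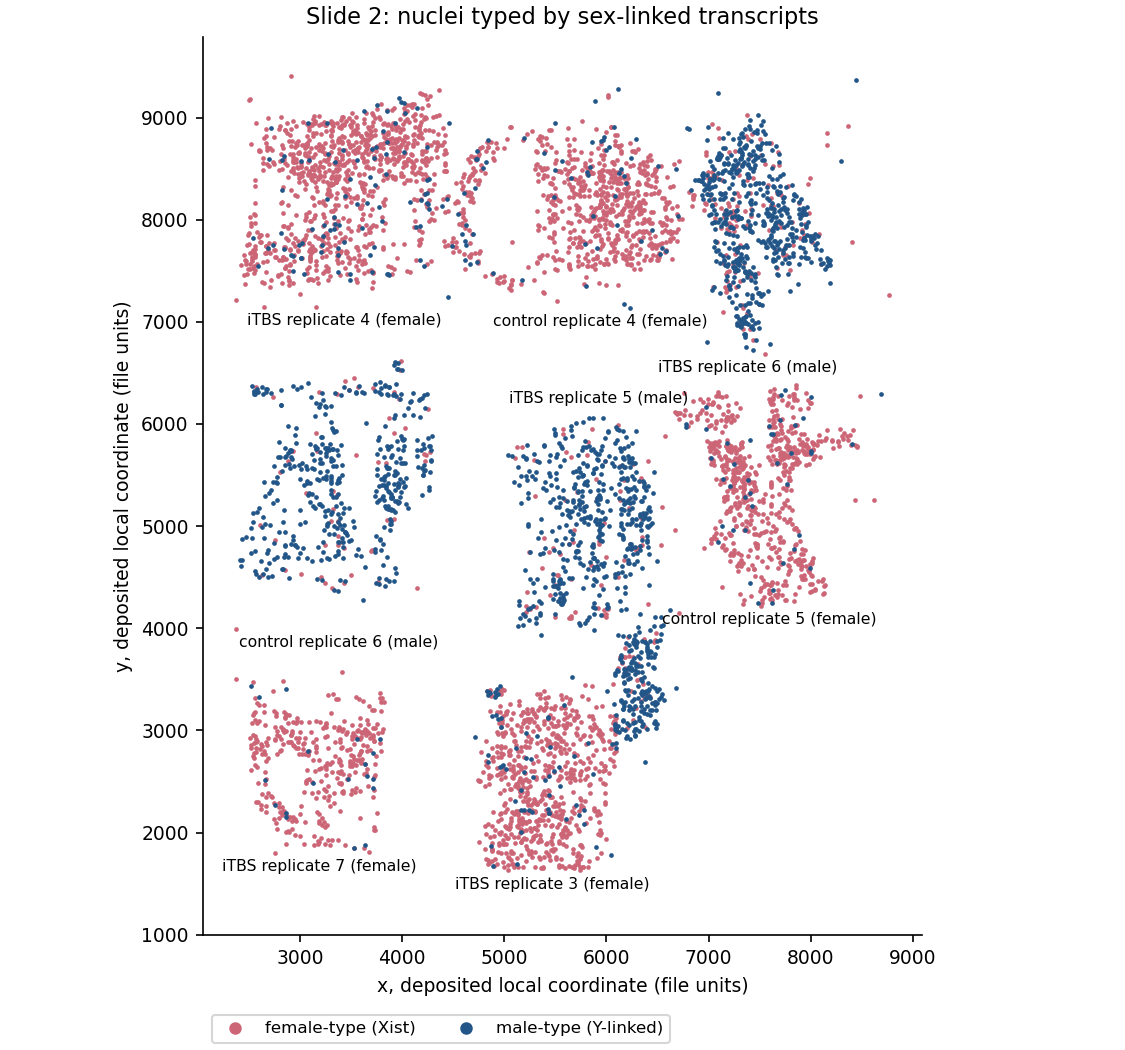
Each point is a typed nucleus of slide 2 at its deposited local position (x and y axes, file units), coloured by female type (Xist) or male type (Y-linked counts), with each animal's name and recorded sex beside its section. In iTBS replicate 3, 214 of 906 typed nuclei are of the other sex.

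The tables hold 1 feature called Virus, whose sequence is not given in the sources used here. It took 0.110% of all UMIs, and 38.2% of nuclei had at least 1 count. Pooled over animals, microglia were most often positive, at 82.8% (exact 95% interval 81.1 to 84.4) despite a median of 1308 UMIs, and at 81.2% after thinning to 1000 UMIs, which left out 473 nuclei. Single animals differed: after thinning, layer 2/3 IT neurons of control replicate 2 were at 76.2% and its microglia at 70.2%, and in iTBS replicate 8 the level per 10000 UMIs was 30.9 in layer 2/3 IT neurons and 17.1 in microglia. Astrocytes were positive in 61.7% (51.4% thinned), layer 2/3 IT neurons in 37.1% (30.7%) and layer 6 IT neurons in 5.06% (3.89%), the latter with a median of 5154 UMIs. The Virus share of all counts was 0.0955 ± 0.0413% in iTBS animals and 0.140 ± 0.0847% in controls (SD, n = 8 and 7; exact permutation p = 0.217). In microglia it was 36.6 ± 9.88 and 55.3 ± 36.0 per 10000 UMIs (exact p = 0.123). Over 4 such comparisons the lowest adjusted p was 0.429.

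**Figure D5:**
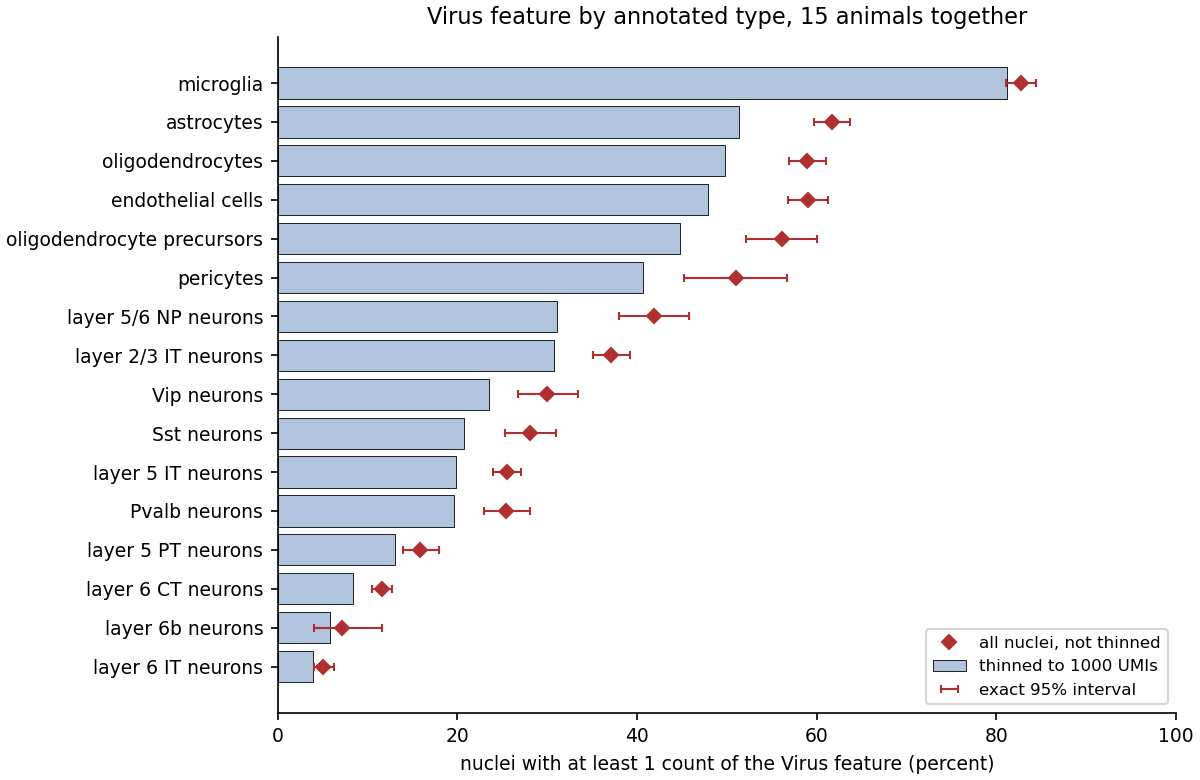
Bars give the percentage of nuclei with at least 1 Virus count (x axis) for each annotated type (y axis) after thinning to 1000 UMIs, and diamonds give it without thinning with exact 95% intervals, for 15 animals together. Microglia stand at 81.2% thinned and layer 6 IT neurons at 3.89%.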

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

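The tests on the Sst neurons of control replicate 1 and the levels of Meis2, Foxp2, Adarb2, Pbx3, Tshz1 and Sox6 were chosen only after the result was seen. Of 110 groups of 4 to 10 animals, 19 held an animal farther from the rest than Dixon's 95% critical value, and chance gives about 1 in 20.

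Control replicate 1 stood apart in the makeup of its nuclei, 1111 in all. Against the other controls its shares were high for Sst neurons (11.43%), endothelial cells (10.35%) and pericytes (16.56%), and low for layer 5/6 NP neurons (0.36%) and Pvalb neurons (1.26%). Of the 10 nearest nuclei of its Sst neurons, 52.99% were also annotated as Sst neurons. In these neurons it held the highest level of Shisa9 (753.1 CPM) and of Tll1 (127.7 CPM) among controls. Its nuclei annotated as pericytes numbered 184, against 122 in all other animals together. They carried the fibroblast genes Col1a2 (258 CPM), Slc6a13 (168 CPM) and Dcn (129 CPM), as those of the other animals pooled did (207, 200 and 256 CPM), with less of the fibroblast gene Lum (12.9 against 116 CPM) and of the pericyte gene Rgs5 (67.2 against 281 CPM). The pericyte genes Rgs5 (1407 CPM), Vtn (616) and Pdgfrb (261) were higher in nuclei annotated as endothelial cells than in those annotated as pericytes, so the pericyte label is in doubt beyond this animal as well.

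Without that animal the fold of Shisa9 in Sst neurons was −0.97 instead of −1.49, the smallest over animals left out, and Tll1 was under the filter on low counts, but 0 genes also passed without any of several other animals. Few nuclei are argued against, because control replicate 1 had 127 annotated Sst nuclei, the most of the 15 animals. A candidate explanation is that many of these nuclei are of another kind: Grin3a, a marker fixed in advance, was at 131 CPM against 582 to 1282 in the other 14 animals, and Sst (375 against 501 to 2307) and Elfn1 (39.0 against 98.2 to 256) were also below all of them. Meis2 (2831 against at most 670 CPM), Foxp2 (776 against 345), Adarb2 (1781 against 387), Pbx3 (1590 against 375) and Tshz1 (489 against 150) were above all other animals and Sox6 (79.7 against at least 575) below them, while of the striatal markers Drd1 (1.77 CPM against a median of 7.84), Drd2 (3.54 against 7.44) and Rgs9 (21.2 against 66.9) were lower and Ppp1r1b and Adora2a (3.54 CPM each, against 0) higher. A difference between the treatments in Sst neurons themselves stays open (Shisa9 at an adjusted p of 0.153 in edgeR without this animal).

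On slide 3, whose nuclei had fewer UMIs, iTBS replicate 8 had the lowest median UMI count of its group (1715) and the highest Apobec4 in glutamatergic neurons (54.71 CPM), Pigk in astrocytes (468.5 CPM) and share of same-type neighbours of Sst neurons (10.45%). The other animal of that slide, control replicate 7, had the highest Pigk of the controls (706.7 CPM). In layer 5/6 NP neurons, control replicate 6 had 1488 CPM of Npy and 671.1 CPM of Sst, and iTBS replicate 2 had 62.12 CPM of Npy, each the highest of its group. In glutamatergic neurons iTBS replicate 2 had the highest Gfap of its group (12.79 CPM), and control replicate 2 the highest mean log2 CPM of the interferon response genes among controls (2.767). In Sst neurons iTBS replicate 1 had the highest Tll1 of its group (26.43 CPM).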

How the results depend on the processing

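The runs without nuclei of the other sex were chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because the replicate numbers of the labels are lanes of pooled nuclei, and each lane holds animals of both groups. Of 374 alternatives for 25 counts, 284 stayed within 1.5 times the main count and 90 did not. Most main counts were 0, and a count of 0 that stayed 0 was scored as within this range. Leaving out single animals moved the count out of the range in 14 of 15 fits in Sst neurons and 13 of 15 in astrocytes. It did so in 2 of 14 fits in NP neurons and 4 of 15 over all types. The filter on low counts mattered most: without it 54 genes passed in glutamatergic neurons (53 of them tested in both), 62 in GABAergic neurons and 404 over types. By type these were layer 2/3 IT 27, layer 5 IT 60, layer 5 PT 25, NP 15, layer 6 IT 19, layer 6 CT 35, Pvalb 5, Sst 38, Vip 6, astrocytes 71, oligodendrocytes 18, their precursors 3, microglia 64 and endothelial cells 18; the cause was not tested. DESeq2 called 1 gene in glutamatergic neurons, 4 in layer 5 IT neurons and 0 in NP and Sst neurons. Without the slide term 0 genes passed in NP neurons, Sst neurons, astrocytes and over all types, and 1 list did; the cause was not tested. Without slide 3, 1 gene passed in GABAergic neurons. Lists passed 0 times with an estimated correlation, with fry, and with an estimated correlation without nuclei of the other sex. Without those nuclei 1 gene passed in layer 6 CT neurons (Gfap, 3.15), 1 in Pvalb neurons (Gpc6, −0.85) and 0 in Sst neurons and astrocytes, where the folds of Tll1 (−2.12), Shisa9 (−1.38) and Pigk (−0.61) stayed close to those with all nuclei.

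Leaving out each animal in turn gave 0 to 1 genes in glutamatergic neurons (1 without iTBS replicate 1), 0 to 2 in GABAergic, 0 to 1 in layer 2/3 IT, 0 to 2 in layer 5 IT, 0 to 4 in layer 5 PT, 0 to 4 in NP, 0 to 1 in layer 6 IT and 0 to 5 in layer 6 CT neurons. It gave 0 to 6 in Sst neurons, 0 to 4 in astrocytes, 0 to 1 in oligodendrocytes, 0 to 2 in microglia, 1 to 15 over all types, and 0 in the other tested types and in shares. Of 275 alternatives for 17 named genes, 270 kept the direction of the fold and 5 reversed: without the slide term Fos (0.16), Egr1 (0.12) and Nr4a1 (0.0239), and without iTBS replicate 2 Fos (0.0023) and Egr1 (0.0189), none past the threshold. Over single animals left out, Fos ran from −0.35 to 0.0023 and Egr1 from −0.22 to 0.0189. In NP neurons 20% of simulated changes of 1.5-fold were recovered against 64% in glutamatergic neurons. Recovery did not follow depth alone, with 36% in layer 6 CT neurons (median 877519 counts per animal) and 44% in astrocytes (466435). The cause was not tested.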

Other observations

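The tests on the Virus feature, on nuclei of the other sex and on the interferon genes per animal were chosen only after the result was seen, and the splits of the animals were planned.

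By camera with the preset correlation, interferon response genes lay higher in iTBS animals in several cell types besides the pooled glutamatergic neurons, and each of these calls was lost with an estimated correlation. In layer 6 corticothalamic neurons all 9 measured genes had fitted values above 0, with a median of 1.06 (camera adjusted p = 1.36e-15; adjusted p = 0.0856 with an estimated correlation), and 6 were called when adjusted over the list alone. All 7 were above 0 in layer 6 IT neurons (median 0.80, adjusted p = 0.000199; adjusted p = 0.213 with an estimated correlation) and all 8 in Sst neurons (0.50, adjusted p = 0.00687; adjusted p = 0.43 with an estimated correlation). Among glia, 21 of 22 were above 0 in astrocytes (0.60, adjusted p = 2.04e-08; adjusted p = 0.308 with an estimated correlation), 9 of 9 in oligodendrocytes (0.55, adjusted p = 3.82e-07; adjusted p = 0.629 with an estimated correlation) and 18 of 20 in microglia (0.30, adjusted p = 2.85e-05; adjusted p = 0.457 with an estimated correlation). Layer 2/3 IT neurons had 8 of 10 above 0 (0.35, adjusted p = 0.0276; adjusted p = 0.571 with an estimated correlation) and GABAergic neurons together 9 of 9 (0.23, adjusted p = 0.0226; adjusted p = 0.467 with an estimated correlation). The list did not pass in endothelial cells (13 of 23, 0.02, adjusted p = 0.441), layer 5 IT (7 of 10, 0.21, 0.785), layer 5 PT (6 of 8, 0.39, 0.113), NP (2 of 5, −0.30, 0.773), Pvalb (2 of 4, 0.19, 0.886) or Vip neurons (3 of 4, 0.58, 0.0629), nor in oligodendrocyte precursors (2 of 5, −0.03, 0.636). Whether these types differ from each other was not tested. They come from the same 15 animals, so their results are not independent, and no splits were run for this list in them. In glutamatergic neurons 63 of the other splits described below also gave this list a camera p under 0.05. The mean log2 CPM of the interferon genes per animal did not pass between treatments in any of the 4 cell sets compared: the exact permutation p was 0.196 in astrocytes, 0.163 in oligodendrocytes, 0.240 in microglia and 0.183 in glutamatergic neurons, each adjusted to 0.240.

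In the same 4 sets this mean was set against the log10 Virus share of all counts of the animal. In microglia Pearson's r was 0.795 (permutation p = 0.00068, adjusted p = 0.00272, n = 15) and Spearman's rho 0.579 (p = 0.0267, adjusted p = 0.107). In astrocytes r was 0.611 (permutation p = 0.0153, adjusted p = 0.0305), in oligodendrocytes 0.525 (p = 0.0435, adjusted p = 0.058) and in glutamatergic neurons 0.154 (p = 0.587). Without the 2 animals farthest from the median Virus level r in microglia was 0.437 (permutation p = 0.137), and over the 8 animals of slide 2 it was 0.203 (exact p = 0.623). Leaving out these animals also narrows the range of Virus levels. With slide means removed and permutation within slides, r was 0.748 in microglia (p = 0.0194, adjusted p = 0.0775) and 0.624 in astrocytes (p = 0.071, adjusted p = 0.142), so 0 sets passed.

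The interferon mean of an animal was also set against its mean of microglia transcripts in the same nuclei. In glutamatergic neurons r was 0.624 (permutation p = 0.0142, adjusted p = 0.0283, n = 15), and with slide means removed and permutation within slides 0.856 (p = 0.00033, adjusted p = 0.00132). In astrocytes r was 0.666 (permutation p = 0.00626, adjusted p = 0.025) and 0.683 within slides (permutation p = 0.0348, adjusted p = 0.0603), and in oligodendrocytes 0.0138 (permutation p = 0.963). In microglia themselves it was −0.284 (permutation p = 0.309) and −0.617 within slides (permutation p = 0.0453, adjusted p = 0.0603). Whether RNA of microglia adds to the interferon counts of neurons was not tested.

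Nuclei with sex-linked transcripts of the other sex made up between 7.22% and 20.5% of deep glutamatergic nuclei (at least 5000 UMIs) in males and between 1.48% and 18.9% in females. Xist has more counts than the Y-linked genes, so the ranges of males and females are not directly comparable. Free RNA as the only source is argued against, because Xist was absent from 58.2% to 88.8% of these nuclei in males, at least 49.6 percentage points above the share that an even spread of their Xist counts would give. Some free Xist RNA is not excluded in iTBS replicate 8. There 86.6% of the Xist counts lay in nuclei with at least 4 of them, against 98.2% to 99.3% in the other males. Doublets of a male and a female nucleus are argued against too, since 12.9% of the 295 deep glutamatergic nuclei of males with at least 4 Xist counts had at least 2 Y-linked counts, against 67.2% of the other 1883. In iTBS replicate 3 nuclei of the other sex lay at a median distance of 502 from the nearest nucleus of another animal, against 1142 for its other typed nuclei (permutation p = 0.0001, the smallest these can give; adjusted p = 0.0015), and for 95.8% that animal was the male iTBS replicate 5, so nuclei of the neighbouring section may have been assigned to it. For the other animals this cannot be told apart. Nuclei of the other sex were nearer at a permutation adjusted p under 0.05 in 5 of 14 (control replicate 1 and iTBS replicates 1, 4, 5 and 6). By median distance they were nearer in 11 of all 15 animals, iTBS replicate 3 included, but not in iTBS replicate 8. For 74.7% of those in the female iTBS replicate 4 the nearest animal was also female, and no biological explanation was tested.

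The high share of microglia with Virus counts is argued not to come from free RNA that enters all nuclei alike. It was 82.8% against 5.06% in layer 6 IT neurons without thinning, where a fixed amount per nucleus would give like shares. After thinning, where an amount in proportion to depth would do so, it was 81.2% against 3.89%. Free RNA that enters types unequally is not judged by these shares. Mitochondrial counts averaged 3.38% per nucleus in microglia and 0.449% in layer 6 IT neurons. RNA carried into microglia with the average content of glutamatergic nuclei is argued against as well. Microglia had 6.42 Virus counts per count of glutamatergic markers and those neurons 0.936, a ratio of 6.85, while astrocytes had 2.77. RNA from the neurons with Virus counts alone could hold more Virus per marker count, as only 5.06% of layer 6 IT neurons were positive. Neuronal RNA of that kind cannot be judged by this ratio. Whether a mouse transcript was counted under this feature cannot be told apart from a viral one: over the animals of slide 1 the level in microglia ranged 2.96-fold, close to the 2.46-fold of the microglial gene Csf1r, and on slide 2 it ranged 3.82-fold against at most 2.33-fold for 5 microglial genes. Both groups were injected, the levels in microglia did not pass between them (exact permutation p = 0.123), and no biological explanation was tested.

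The number of genes past the threshold was counted again in random splits of the animals within slides into groups of the same sizes. The real grouping is 1 of the splits in each count below. For glutamatergic neurons (0 genes) all 100 splits gave as many, with 2 as the highest other, and for GABAergic neurons (0) all 100, with 26. Every split matches a count of 0, so for such counts the splits test nothing. The 6 genes over all types were matched in 14 of 30 splits (highest other 45), the 3 in NP neurons in 8 of 30 (4), the 2 in Sst neurons in 4 of 30 (17) and the 1 in astrocytes in 4 of 30 (39), so chance is not excluded for these counts. Types with 0 genes were by necessity matched in all 30 splits, or all 21 for layer 6b neurons. Their highest other counts were 43 in layer 2/3 IT, 1 in layer 5 IT, 4 in layer 5 PT, 8 in layer 6 IT, 5 in layer 6 CT, 0 in layer 6b, 1 in Pvalb and 4 in Vip neurons, and 6 in oligodendrocytes, 1 in their precursors, 17 in microglia and 4 in endothelial cells. A highest count several times the real one, as with 39 in astrocytes, shows how far such counts vary between groupings. In astrocytes 3 of the other splits called any gene. Whether a structure of the samples other than treatment lies behind this was not tested.

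The 10 lists in glutamatergic neurons were matched in 25 of 100 splits (highest other 19), and the interferon list had a camera p as small as its real 2.63e-09 in 24 of 100, so chance is not excluded for either. Of the other splits, 98 passed at least 1 list. A camera p under 0.05 for the interferon list came from 63 other splits, the smallest at 4e-26. With the preset correlation, camera thus gave small p in many groupings of these animals. Differences between classes of neurons (0 genes each) were by necessity matched in all 100 splits, with highest others of 0 for glutamatergic against GABAergic neurons and 3 for IT against other glutamatergic neurons. The 54 genes in glutamatergic neurons without the filter on low counts were matched in 5 of 30 splits (highest other 653), so chance is not excluded there either. The 6 genes between sexes were matched in 2 of 100 splits, which excludes chance at 0.05. The highest other, 426 genes, placed control replicate 3 and iTBS replicates 2, 4, 6, 7 and 8 together, most of them iTBS animals. Whether treatment or another structure of the samples lies behind it was not tested.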
